A study of Mus musculus with 10 samples.

How the data were processed

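Splenic B cells of mice with both Irf4 alleles intact (Irf4+/+) or with both disrupted (Irf4-/-) were compared on 1-colour Affymetrix 3′ expression arrays, with 5 arrays per genotype. Per the labels' protocols, the mice were littermates of 12 weeks on a C57BL/6 background. Non-B cells were removed magnetically from spleen cells, and the remaining cells were cultured for 3 days with an antibody against CD40 and with IL-4 at 20 ng/ml. Biotin-labelled cRNA was made from 6 ug of total RNA per sample. The labels do not say whether the 5 samples of a genotype came from separate mice or separate cultures, so p-values measure the spread between these samples, which may be technical.

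The deposited values are linear signal intensity values, 1 per probe set and array. They were made with MAS5, per the submitters' processing notes, and its version and scaling target are not given in the sources used here. On every array the mean after removing 2% of the values at each end was 250, so the arrays were taken as already scaled. A MAS5 signal combines perfect-match and mismatch probes, and dim signals are noisy on the log scale. Arrays have no read depth, and their number, 5 per genotype, limits the precision. The median SD of the log2 values within a genotype was 0.17 in Irf4+/+ and 0.16 in Irf4-/- samples.

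The table held 45101 probe sets, of which 64 were controls. In the platform annotation 34945 probe sets had 1 gene symbol, 932 had several and 9160 are not named here. Symbols were brought up to date through gene IDs in a RefSeq gene table of assembly GRCm38.p6, which held the ID of 34741 of the 1-symbol probe sets. That table also gave the order of genes along the chromosome. Only probe sets with 1 symbol entered the gene tests, and no genome build is named for the arrays, so no coordinates are given.

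Values were transformed to log2(signal + 7.9), where 7.9 is the 20th percentile of all deposited values. Fold changes are on this scale, which understates the change of dim genes. The fold of any gene with a group mean near or under 26.1, the 40th percentile of all values, depends on the pseudocount. Probe sets under the 40th percentile of the mean over all 10 arrays were left out. For each gene the probe set with the highest mean over all arrays was used, which left 12246 of 18193 genes, and 5947 genes had only dim probe sets. A linear model with moderated variances was fitted in limma 3.58.1 (lmFit, and eBayes with a mean-variance trend) under R 4.3.3. It had genotype as its single term and no further normalization between arrays. Two-sided p-values were adjusted over all genes by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05, and the number at least 2-fold is given beside that count. All adjusted p-values for genes are from this limma fit unless stated otherwise.

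The 30 gene lists cover plasma cell differentiation, class switch recombination machinery, immunoglobulin constant regions, germinal centre, resting follicular and marginal zone B cells, responses to IL-4 and CD40, mitosis, DNA replication, MYC targets with ribosome biogenesis, glycolysis, oxidative phosphorylation, the endoplasmic reticulum, cholesterol synthesis, MHC class II presentation, the interferon response, B cell receptor signalling, B cell transcription factors, apoptosis, migration, the p53 response, immediate early genes with heat shock genes, and markers of T cells, natural killer cells, macrophages, dendritic cells, granulocytes, erythroid cells with platelets, and stromal cells. They were tested with camera in limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Genes within 50 annotated genes on either side of Irf4 were compared with all other genes by Fisher's exact test. Single measures of the arrays were compared by exact two-sided permutation tests, whose smallest p for 5 against 5 is 0.00794.

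The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names Irf4, and the 10 called genes with the largest positive and the 10 with the largest negative log2 fold change among those whose groups do not overlap, leaving out predicted models. It also names up to 4 members of each list with the smallest p, a set of B cell regulators whatever their result, the sex-linked genes and the called neighbours of Irf4. Other members of the lists named in the text were chosen after their values were seen. The alternatives were other pseudocounts, filters and scalings, other variance models, array weights, the replicate number as a block, other ways of choosing probe sets, and each array left out. The text on sensitivity gives their effect.

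The procedure was tested on simulated data for 12246 genes with the means and spreads of the real genes. It recovered 74% of 50 genes changed 1.5-fold, 80% of 100 genes changed 2-fold and 92% of 50 genes changed 4-fold. In that simulation 8 of 188 calls were false, the list that had been shifted was called, and 0 of the 29 other lists were. The simulated genes varied independently of each other and most were unchanged, unlike the real genes. False calls of lists whose genes are correlated were therefore not checked. Figures were drawn with matplotlib 3.10.9. Probe sets with several symbols or not named here were left out of the gene tests. Ighg1, Ighe and Ddx3y had no 1-symbol probe set used here.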

Results

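Irf4 encodes a transcription factor of the interferon regulatory factor family that B cells induce on activation. There are 5 Irf4+/+ and 5 Irf4-/- samples of cultured splenic B cells, and whether those of a genotype are separate cultures is not given. The cells were stimulated for 3 days through CD40 and the IL-4 receptor, a combination that drives B cells to divide and switch antibody class. The comparison asks which transcripts differ between the genotypes under this stimulation. Array medians were 40.6 ± 2.23 signal units in Irf4+/+ and 42.7 ± 1.87 in Irf4-/- samples (SD, n = 5; exact permutation p = 0.175, adjusted p = 0.218 over 5 array measures). Pearson's r between arrays over the tested genes was 0.978 to 0.985 within a genotype and 0.94 to 0.946 between genotypes.

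The ratio of 3′ to 5′ signal, a sign of RNA integrity, was 1.15 ± 0.0258 for the Actb control in Irf4+/+ and 1.10 ± 0.0227 in Irf4-/- samples (SD, n = 5; exact permutation p = 0.0238, adjusted p = 0.0595). For the Gapdh control it was 0.856 ± 0.0269 and 0.859 ± 0.0404 (exact permutation p = 0.873, adjusted p = 0.873). The signal of the 18S ribosomal RNA control was 69.0 ± 20.2 in Irf4+/+ and 207.1 ± 66.1 in Irf4-/- samples, 3.00-fold higher (exact permutation p = 0.00794, the smallest 5 against 5 can give; adjusted p = 0.0397). Xist was bright in all 10 arrays and the probe sets of the Y-linked genes Kdm5d, Eif2s3y and Uty were dim in all 10. Xist had a log2 fold change of 0.30 (SE 0.133, adjusted p = 0.0722), and was called without Irf4+/+ replicate 1 or 5 or Irf4-/- replicate 4, with adjusted p from 0.00794 to 0.199 over the arrays left out.

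Irf4 transcript was still measured in Irf4-/- samples. Its brighter probe set gave 3761 ± 211 in Irf4+/+ and 2792 ± 128 in Irf4-/- samples (SD, n = 5), or 74.2% of the Irf4+/+ level. The log2 fold change was -0.43 (SE 0.0536, adjusted p = 4.98e-06), and all Irf4-/- arrays lay below all Irf4+/+ arrays. The dimmer probe set gave 425.8 ± 79.0 and 325 ± 91.4, 76.3% of the Irf4+/+ level (exact permutation p = 0.0952, and adjusted p = 0.0504 in limma over all probe sets). Where these probe sets lie relative to the disrupted part of the gene is not given in the sources used here, so their signal does not check the genotype.

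Across the transcriptome the genotypes differed widely. Of 12246 genes, 5764 were called (47.1%), 2846 higher and 2918 lower in Irf4-/- samples, and 6454 had an unadjusted p under 0.05. Many of these differences were small: 3372 called genes changed by less than 1.5-fold. At least 2-fold changes were counted for 948 genes, 644 higher and 304 lower, and at least 4-fold changes for 170 higher and 36 lower. The groups did not overlap for 4352 genes, of which 4305 were called, where chance gives 0.794% of genes.

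The strongest falls included secreted and surface proteins. Mpzl2, an adhesion protein, fell from 806.4 ± 178 to 4.90 ± 3.32 (64.2-fold), and Slpi, a secreted inhibitor of leukocyte proteases, from 3566 ± 389 to 80.6 ± 7.65 (40.3-fold; SD, n = 5). Jchain, which joins IgM and IgA into polymers, fell 35.2-fold and Cd93, a surface protein of plasma cells, 30.5-fold. Gnaz (14.8-fold), Endou (14.2-fold), the transcription factor Lef1 (12.6-fold), Hacd1 (11.4-fold), the actin-severing protein Scin (11.1-fold) and the DNA glycosylase Neil1 (10.4-fold) followed. Adjusted p was at most 1.66e-09 (Gnaz) for these 10 genes.

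The strongest rises included interferon-inducible and myeloid genes. Chil3, a chitinase-like protein of macrophages, rose from 4.66 ± 3.85 to 364.8 ± 74.6 (30.2-fold), and the interferon-inducible genes Rtp4 and Iigp1 rose 27.9-fold and 25.1-fold (SD, n = 5). Ms4a4c rose 22.9-fold, the cytokine receptor Lifr 22.3-fold, Parp12 21.8-fold, Serpinb1a 20.5-fold, Csrp3 20.5-fold, Lyz1 17.4-fold and Calhm6 15.8-fold. Adjusted p was at most 4.70e-08 (Csrp3). Chil3, Rtp4, Lifr, Parp12, Serpinb1a, Csrp3, Lyz1 and Calhm6 were close to the floor of the array in Irf4+/+ samples, and Mpzl2 and Jchain in Irf4-/- samples. Cd93, Gnaz and Scin were also dim in Irf4-/- samples (means 34.4, 36.0 and 36.4). For all these genes the size of the fold depends on the pseudocount.

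**Figure D1:**
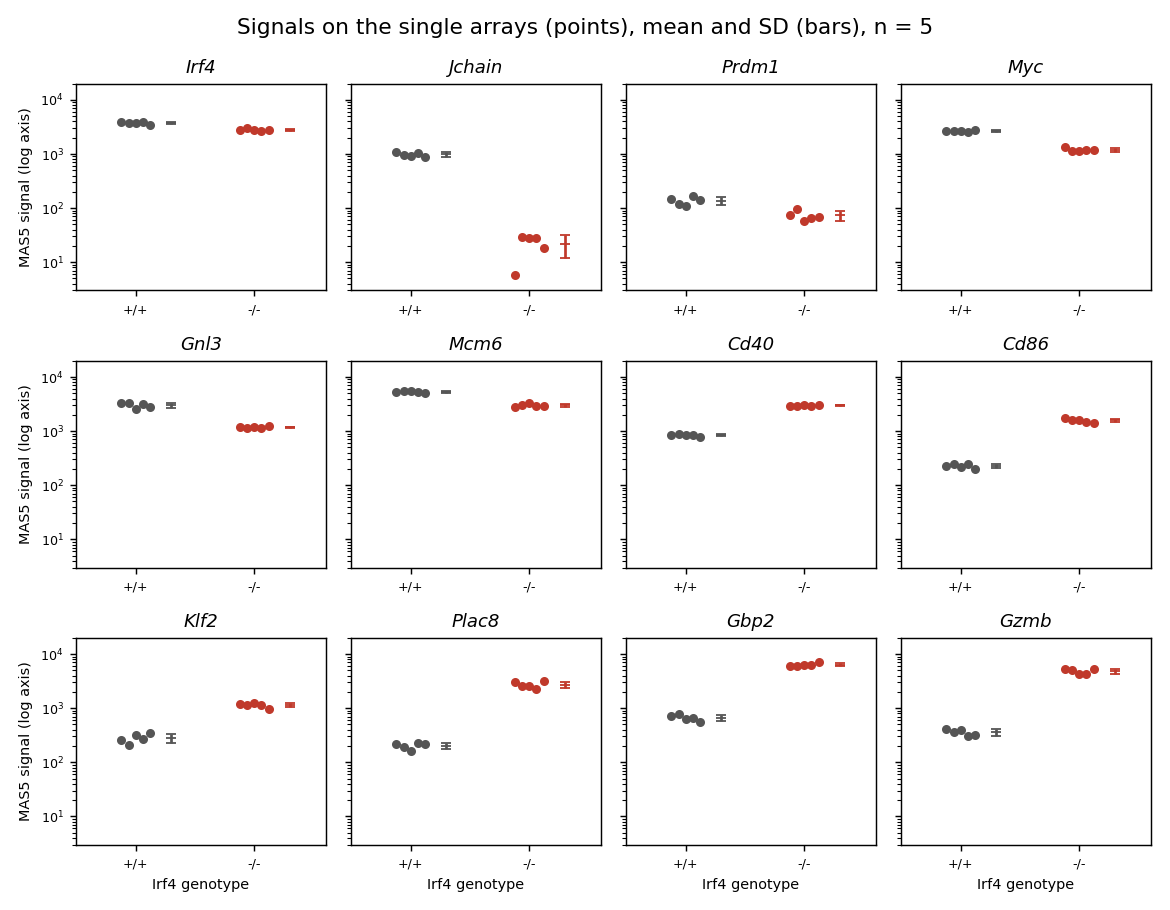
MAS5 signal (log axis, the same for all panels) of 12 genes on the 5 Irf4+/+ and 5 Irf4-/- arrays, with points for arrays and bars for the mean and SD. Irf4, Jchain, Prdm1, Myc, Gnl3 and Mcm6 lie lower in every Irf4-/- array than in any Irf4+/+ array, and Cd40, Cd86, Klf2, Plac8, Gbp2 and Gzmb higher.

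Gene lists answer whether known programmes of B cells moved together. Of the 30 lists, 21 were called by camera, 13 higher and 8 lower in Irf4-/- samples, and 15 of them with an estimated correlation. Fry, which does not set a list against other genes, called 26.

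Plasma cell genes were lower. Of 21 tested members 13 fell, 5 rose and 3 were not called (adjusted over the list alone, 13 fell and 6 rose). Beside Jchain and Cd93, Prdm1, the regulator of plasma cell fate, fell 1.80-fold from 138.0 ± 24.0 to 73.2 ± 15.2, Sdc1, the plasma cell surface proteoglycan, 2.04-fold, and Eaf2 2.43-fold. Xbp1, which expands the secretory apparatus, fell 1.15-fold (log2 fold change -0.20, adjusted p = 0.00421), and with the probe sets shared between transcripts left out its value was 0.01 (adjusted p = 0.956). Ell2, an elongation factor for immunoglobulin transcripts, rose 1.85-fold. The list had a median log2 fold change of -0.58 (camera adjusted p = 0.00624, and adjusted p = 0.104 with an estimated correlation). In Irf4-/- samples natural killer and macrophage markers were also higher (medians 1.91 and 1.46), as was the 18S control (3.00-fold).

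Genes of class switch recombination were lower, by small amounts. Of 23 members 13 fell, 3 rose and 7 were not called, with the same numbers adjusted over the list alone. The DNA damage kinase Atm fell 1.54-fold, the exonuclease Exo1 1.75-fold and the end-protection factor Rif1 1.48-fold, and Batf, a transcription factor of activated lymphocytes, rose 1.55-fold. A second Atm probe set had the opposite sign. The median was -0.22 (camera adjusted p = 0.0228, and adjusted p = 0.159 with an estimated correlation). Of the 4 immunoglobulin constant region and joining genes tested, Ighg3 rose 4.34-fold from 86.8 ± 10.8 to 401.6 ± 25.4 and Jchain fell, and the list was not called (median 0.20, camera adjusted p = 0.547). Adjusted over the list alone, 2 rose and 1 fell. Ighm rose 1.37-fold on its brightest probe set, but 6 of its 10 probe sets had the opposite sign, and immunoglobulin probe sets can bind related transcripts, so the direction of Ighm and Ighg3 is uncertain. Igha had a log2 fold change of -0.06 (adjusted p = 0.841) on its brightest probe set. It was called lower with the mean of its probe sets (-1.20, adjusted p = 8.09e-05) and without probe sets shared between transcripts (-1.38, adjusted p = 0.000979).

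Genes of germinal centre and resting follicular B cells were higher on balance. In the germinal centre list 10 of 16 members rose, 4 fell and 2 were not called, also adjusted over the list alone. The transcription factors Lmo2, Spib and Bcl6 rose 2.56-fold, 2.42-fold and 1.55-fold (Bcl6 from 513.6 ± 40.9 to 802.2 ± 85.9), and Ebi3, a cytokine subunit, rose 1.95-fold, while Basp1 fell 2.50-fold. Its median was 0.41 (camera adjusted p = 0.0283, and adjusted p = 0.104 with an estimated correlation). In the resting follicular list 13 of 21 rose, 6 fell and 2 were not called, also adjusted over the list alone. Klf2, a regulator of lymphocyte quiescence and homing, rose 4.07-fold from 279.9 ± 56.4 to 1148 ± 107, the chemokine receptor Ccr6 7.53-fold and the signalling adaptor Bank1 3.40-fold, while the chromatin organizer Satb1 fell 4.96-fold. Its median was 0.48 (camera adjusted p = 0.0321, and adjusted p = 0.0806 with an estimated correlation). Between the same 2 genotypes, natural killer and macrophage markers were also higher in Irf4-/- samples (medians 1.91 and 1.46).

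Marginal zone and Notch2 pathway genes rose together. Of 17 members 13 rose, 1 fell and 3 were not called, also adjusted over the list alone. Plac8 rose 12.9-fold from 203 ± 26.3 to 2718 ± 377, the sphingosine phosphate receptor S1pr3 3.24-fold, Tm6sf1 2.97-fold, Asb2 2.95-fold and Cr2, the complement receptor of marginal zone cells, 1.56-fold. Notch2 itself rose 1.32-fold on its brighter probe set, and the mean of its probe sets gave a log2 fold change of -0.10 (adjusted p = 0.505). The median was 0.77 (camera adjusted p = 7.99e-06, and adjusted p = 0.024 with an estimated correlation). Natural killer and macrophage markers were higher in the same samples (medians 1.91 and 1.46).

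Transcripts that respond to the stimuli themselves were higher. In the IL-4 and STAT6 list 14 of 20 members rose, 0 fell and 6 were not called, and 15 rose adjusted over the list alone. The chemokine Ccl17 rose 11.2-fold from 17.6 ± 14.0, close to the floor, the zinc transporter Slc39a8 5.90-fold, the feedback inhibitor Socs1 3.54-fold, Fcer2a (the low-affinity IgE receptor) 1.86-fold from 6828 ± 425 to 12710 ± 905, the receptor chain Il4ra 1.65-fold, Nfil3 1.89-fold and Ccl22 1.31-fold. Its median was 0.54 (camera adjusted p = 1.03e-06, and adjusted p = 0.0412 with an estimated correlation). In the CD40 and NF-kB list 22 of 30 rose, 5 fell and 3 were not called, also adjusted over the list alone. Cd40 rose 3.52-fold from 839.4 ± 31.8 to 2977 ± 86.4, the costimulatory ligand Cd86 6.75-fold, the NF-kB cofactor Bcl3 4.02-fold and Slamf1 2.25-fold. The other costimulatory ligand, Cd80, fell 4.15-fold from 431.4 ± 57.9 to 98.0 ± 13.1 (log2 fold change -2.05, adjusted p = 2.56e-10). Ccr7, Junb, Rel and Tnfaip3 also fell (log2 fold changes -0.59, -0.47, -0.18 and -0.16), and these 5 genes were named after their values were seen. With the mean of its probe sets Tnfaip3 was not called (adjusted p = 0.124). The list's median was 0.41 (camera adjusted p = 6.38e-06, and adjusted p = 0.0403 with an estimated correlation). As a group, the Irf4-/- samples also had higher natural killer and macrophage markers (medians 1.91 and 1.46).

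Growth and division genes fell. All 31 MYC target and ribosome biogenesis genes fell, also adjusted over the list alone. Myc fell 2.19-fold from 2637 ± 88.7 to 1205 ± 93.6, the nucleolar proteins Gnl3 and Nolc1 2.53-fold and 2.14-fold, and the spermidine synthase Srm 2.40-fold. The median was -0.76 (camera adjusted p = 8.66e-17, and adjusted p = 0.000556 with an estimated correlation). Of 35 DNA replication genes 28 fell, 2 rose and 5 were not called (29 fell and 2 rose adjusted over the list alone). The replicative helicase genes Mcm6 and Mcm5 fell 1.78-fold and 1.40-fold, the replication initiation factor Mcm10 1.56-fold and Cdc45 1.55-fold. The median was -0.45 (camera adjusted p = 1.22e-08, and adjusted p = 0.00138 with an estimated correlation). Of 29 mitosis genes 22 fell, 0 rose and 7 were not called (23 fell adjusted over the list alone), among them Hmmr (1.61-fold), Aurkb (1.47-fold), Cdc20 (1.46-fold) and Aurka (1.42-fold). The median was -0.34 (camera adjusted p = 1.40e-06, and adjusted p = 0.0369 with an estimated correlation). The same samples had higher natural killer and macrophage markers (medians 1.91 and 1.46) and a 3.00-fold higher 18S control.

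Glycolysis genes were lower, and those of oxidative phosphorylation moved both ways. Of 19 glycolysis genes 16 fell, 2 rose and 1 was not called, also adjusted over the list alone. The lactate transporter Slc16a1 fell 2.98-fold, Hk2, which phosphorylates glucose, 2.11-fold and Pgam1 1.52-fold, while Aldoc rose 1.67-fold. The median was -0.38 (camera adjusted p = 9.67e-05, and adjusted p = 0.075 with an estimated correlation). Beside this fall, Irf4-/- samples had higher natural killer and macrophage markers (medians 1.91 and 1.46) and a 3.00-fold higher 18S control. Of 48 oxidative phosphorylation genes 8 rose, 14 fell and 26 were not called, also adjusted over the list alone. Cyc1 fell 1.52-fold, Ndufa9 1.23-fold and Atp5b 1.17-fold, and Ndufa4 rose 1.30-fold. The list was not called (camera adjusted p = 0.66, lower), with a median of 0.03 of the opposite sign.

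Genes of the endoplasmic reticulum and its unfolded protein response fell on balance. Of 32 members 21 fell, 5 rose and 6 were not called, also adjusted over the list alone. The coat protein Sec24d fell 3.59-fold, the stress sensor Atf6 1.98-fold, Herpud1 1.62-fold and the chaperone Hsp90b1 1.59-fold from 7804 ± 285 to 4902 ± 175. The median was -0.36 (camera adjusted p = 5.96e-05, and adjusted p = 0.00664 with an estimated correlation). Irf4-/- samples also had higher natural killer and macrophage markers (medians 1.91 and 1.46) and a 3.00-fold higher 18S control. Of 20 cholesterol synthesis genes 4 rose, 7 fell and 9 were not called, also adjusted over the list alone, and the list was not called (median -0.01, camera adjusted p = 0.437). Lss fell 1.89-fold, Cyp51 1.44-fold, Sc5d 1.31-fold and Sqle 1.23-fold, and a further Sc5d probe set had the opposite sign. With the mean of its probe sets Sc5d was not called (log2 fold change -0.12, adjusted p = 0.248).

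Antigen presentation and B cell receptor genes rose. Of 15 MHC class II presentation genes 12 rose, 0 fell and 3 were not called (13 rose and 1 fell adjusted over the list alone). The peptide-loading modulators H2-Ob and H2-Oa rose 3.34-fold and 2.86-fold, and the lysosomal enzymes Lgmn and Ifi30 3.71-fold and 2.18-fold. The median was 0.70 (camera adjusted p = 5.35e-08, and adjusted p = 0.0162 with an estimated correlation). Of 29 B cell receptor signalling genes 23 rose, 3 fell and 3 were not called, also adjusted over the list alone. The inhibitory receptors Siglecg and Cd72 rose 5.18-fold and 2.98-fold, the receptor chain Cd79b 2.21-fold from 5978 ± 286 to 13250 ± 820 and the adaptor Dapp1 2.09-fold. The median was 0.60 (camera adjusted p = 5.81e-08, and adjusted p = 0.00394 with an estimated correlation). In the same samples natural killer and macrophage markers were higher (medians 1.91 and 1.46), and macrophages also express MHC class II genes and Ctss.

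Of 21 B cell transcription factors 13 rose, 3 fell and 5 were not called, also adjusted over the list alone. Id2, which natural killer cells also express, rose 5.15-fold, Pax5, the B cell identity factor, 2.17-fold, Irf8 2.16-fold from 3278 ± 143 to 7087 ± 340, Bach2 1.80-fold and Spi1 1.47-fold. Lef1 fell, as given above. The median was 0.55 (camera adjusted p = 0.000424, and adjusted p = 0.0162 with an estimated correlation). Of 26 migration and adhesion genes 17 rose, 5 fell and 4 were not called (17 rose and 6 fell adjusted over the list alone). The signal regulator Rgs1 rose 3.42-fold and the integrin chains Itgb2 and Itgal 2.42-fold and 2.02-fold. The median was 0.55 (camera adjusted p = 3.89e-05, and adjusted p = 0.0162 with an estimated correlation). These integrin chains are shared by leukocytes, and the natural killer and macrophage markers were higher in the same samples (medians 1.91 and 1.46).

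Genes of the p53 response fell on balance. Of 21 members 14 fell, 3 rose and 4 were not called, also adjusted over the list alone. Plk2 fell 3.01-fold, Zmat3 2.09-fold and Trp53inp1 1.57-fold, while Sesn1 rose 2.91-fold. The median was -0.51 (camera adjusted p = 9.61e-05, and adjusted p = 0.0177 with an estimated correlation). Higher natural killer and macrophage markers (medians 1.91 and 1.46) and a 3.00-fold higher 18S control went with the same genotype. Of 20 apoptosis genes 7 rose, 5 fell and 8 were not called, also adjusted over the list alone, with a median of 0.08 (camera adjusted p = 0.704). Bcl2l11, a promoter of cell death, rose 1.66-fold and Casp9 1.77-fold, and Pmaip1 and Bid fell 1.75-fold and 1.38-fold. Of 20 immediate early and heat shock genes 4 rose, 8 fell and 8 were not called, also adjusted over the list alone, with a median of -0.15 (camera adjusted p = 0.533). Jun rose 2.26-fold, Dusp2 2.29-fold and Egr3 2.88-fold, with another Egr3 probe set of the opposite sign, and the chaperone Hsph1 fell 1.90-fold.

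The interferon response had the smallest p of all lists. Of 29 members 28 rose, 0 fell and 1 was not called, also adjusted over the list alone. The antiviral synthetase Oas1a rose 12.7-fold from 149.6 ± 21.5 to 1975 ± 161, the GTPase Gbp2 9.49-fold from 669.4 ± 85.9 to 6387 ± 402, Parp14 3.12-fold and the transcription factor Irf1 2.44-fold. The median was 1.57 (camera adjusted p = 9.54e-18, and adjusted p = 0.000556 with an estimated correlation). Natural killer and macrophage markers, given next, were higher in the same samples.

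Markers of natural killer cells and macrophages rose in Irf4-/- samples. All 14 natural killer markers rose, also adjusted over the list alone. The cytotoxic granule genes Gzmb, Gzma and Prf1 rose 13.2-fold (362 ± 51.6 to 4868 ± 533), 9.95-fold (818.6 ± 106 to 8256 ± 1380) and 4.91-fold. The receptor Klrd1 rose 6.20-fold (22.8 ± 8.38 to 178.1 ± 28.3), from close to the floor, so the size of its fold depends on the pseudocount. The median was 1.91 (camera adjusted p = 5.35e-08, and adjusted p = 0.00213 with an estimated correlation). Of 16 macrophage and monocyte markers 10 rose, 1 fell and 5 were not called, also adjusted over the list alone. Lyz1 rose as given above, Adgre1 (the F4/80 antigen) 3.87-fold from 153.2 ± 21.0 to 610.9 ± 30.6, Mpeg1 3.59-fold and Cd68 2.60-fold. The median was 1.46 (camera adjusted p = 4.22e-05, and adjusted p = 0.0137 with an estimated correlation).

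Markers of other cell types gave mixed results. Of 8 granulocyte, mast cell and basophil markers 4 rose, 0 fell and 4 were not called, also adjusted over the list alone. S100a9, S100a8 and Ngp rose 14.7-fold, 10.6-fold and 4.33-fold (median 0.53, camera adjusted p = 0.0188, and adjusted p = 0.13 with an estimated correlation), and Mmp9 rose 1.72-fold at an adjusted p of 0.0474. S100a9, S100a8 and Mmp9 were close to the floor in Irf4+/+ samples (6.56 ± 5.02, 18.3 ± 7.87 and 20.7 ± 14.6), so the size of their folds depends on the pseudocount. The Mmp9 call was lost when any array but Irf4+/+ replicate 4 was left out (adjusted p up to 0.119). Of 9 T cell markers 2 rose, 2 fell and 5 were not called, also adjusted over the list alone. Thy1 and Cd2 rose 4.26-fold and 2.82-fold, and Ctla4 and Cd28 fell 3.28-fold and 1.44-fold (camera adjusted p = 0.987, higher, with a median of -0.18 of the opposite sign). Cd2 was close to the floor in Irf4+/+ samples (25.5 ± 9.45), so the size of its fold depends on the pseudocount. Of 10 dendritic cell markers 3 rose, 4 fell and 3 were not called, also adjusted over the list alone. Ccl17, already named in the IL-4 list, rose and the cytokine receptor Flt3 fell 7.13-fold, Fscn1 1.90-fold and Batf3 1.55-fold (median -0.01, camera adjusted p = 0.62).

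Of 8 erythroid and platelet markers 2 rose, 0 fell and 6 were not called, also adjusted over the list alone. Car2 rose 5.13-fold and Ermap 2.99-fold, the latter from 16.6 ± 8.19, close to the floor, so the size of its fold depends on the pseudocount. Haemoglobin Hba-a1 had a log2 fold change of -0.31 (adjusted p = 0.503) and Treml1 of -0.37 (adjusted p = 0.402). The median was 0.04 (camera adjusted p = 0.437). Of 8 stromal and endothelial markers 1 rose, 0 fell and 7 were not called, also adjusted over the list alone. Pecam1 rose 3.75-fold from 24.4 ± 12.7, close to the floor, so the size of its fold depends on the pseudocount. Col1a2 had a log2 fold change of -0.46 (adjusted p = 0.0896, and 0.0413 without Irf4-/- replicate 4), Col4a1 of -0.28 (adjusted p = 0.373) and Cxcl13 of 0.41 (adjusted p = 0.444). The list was not called (camera adjusted p = 0.799, higher, with a median of -0.01 of the opposite sign).

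**Figure D2:**
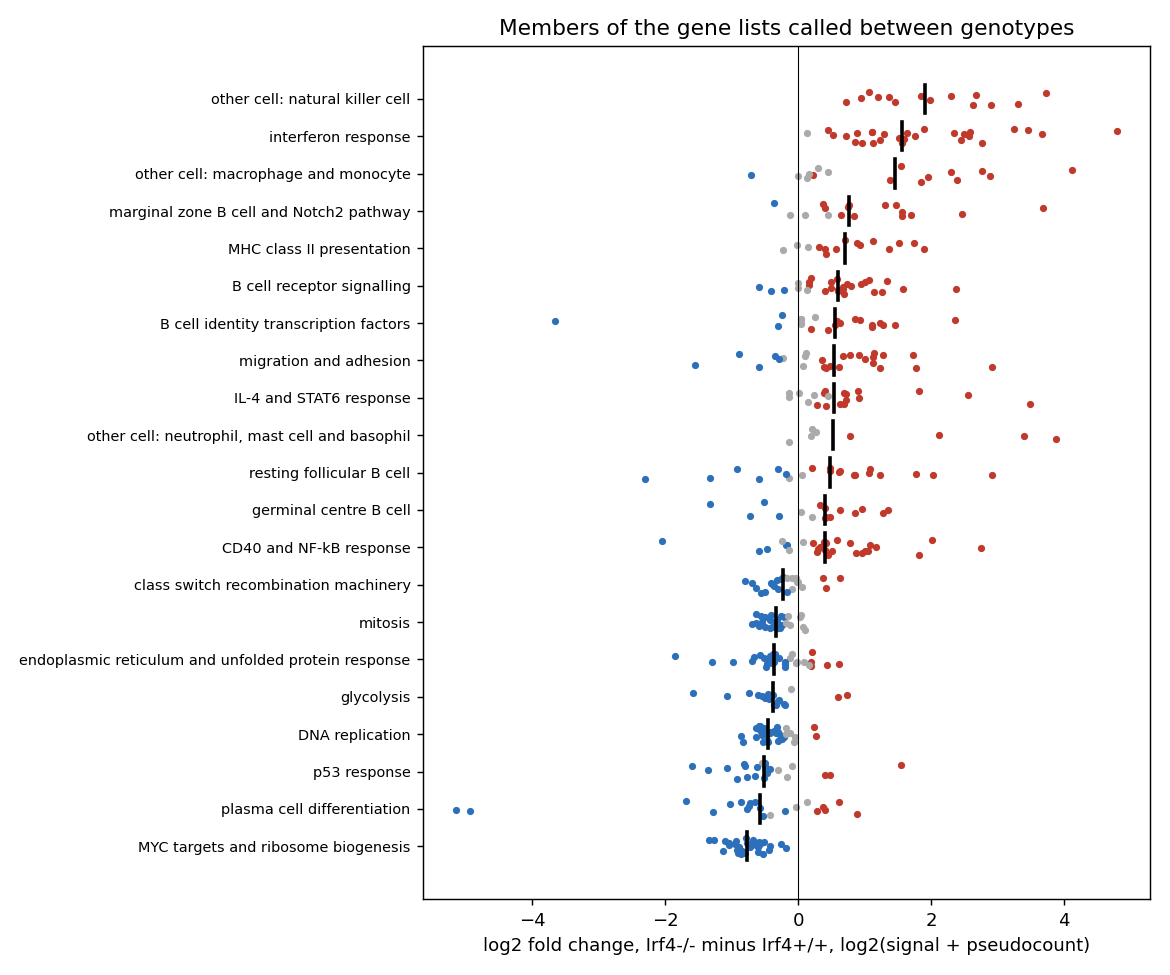
Log2 fold change (Irf4-/- minus Irf4+/+) of each tested member of the 21 lists called by camera, with 1 point per gene (red higher and called, blue lower and called, grey not called) and a bar at the list's median. Natural killer, interferon and macrophage lists lie farthest to the right, with medians of 1.91, 1.57 and 1.46, and MYC targets farthest to the left, at -0.76.

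Genes beside Irf4 on its chromosome were compared with all others, since a targeted allele can carry flanking DNA of the stem cell strain it was made in. Of the 16 tested genes within 50 annotated genes on either side, 8 were called, against 5755 called and 6474 not called elsewhere (odds ratio 1.12, 95% confidence interval 0.368 to 3.44, Fisher's exact p = 1). Serpinb1a rose 20.5-fold, the phosphatase Dusp22 4.59-fold from 177.8 ± 28.5 to 838.8 ± 54.1, and the protease inhibitors Serpinb9 and Serpinb6b 3.70-fold and 3.62-fold. Smaller changes were Serpinb9b (1.89-fold higher), Exoc2 (1.26-fold higher), E2f3 (1.21-fold lower) and Gmds (1.18-fold lower). Without Irf4+/+ replicate 2 or 3 or Irf4-/- replicate 2, 3, 4 or 5, Serpinb9b and Gmds were no longer called, nor was Serpinb9b without Irf4+/+ replicate 5 (adjusted p up to 0.0948 for Serpinb9b and 0.133 for Gmds). With the mean of its probe sets E2f3 was not called (log2 fold change -0.21, adjusted p = 0.0681).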

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

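Tests on a lower share of B cells and on dilution were chosen only after the result was seen, and the other tests were set before their values were seen. Of 100 splits of the 10 arrays into 5 and 5, drawn from 126, 1 gave as many called genes as the real split, namely the real split itself, with 5764 genes. The highest of the other splits gave 1 gene. Every other split mixes the genotypes, which puts their difference into its spread, so few calls there were fixed in advance. Since the 5 samples of a genotype may be technical, a chance difference between mice or cultures is not excluded.

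Markers of natural killer cells and macrophages rose in Irf4-/- samples although the cells had been purified by magnetic removal of non-B cells. A lower share of B cells could raise every other cell type alike, but the medians of the T cell, dendritic, erythroid and stromal lists were at most 0.036. Their upper quartiles, at most 0.54, lay below the lower quartile of the natural killer list, 1.24, but not all below that of the macrophage list, 0.21. Granulocyte markers had a median of 0.53 (camera adjusted p = 0.13 with an estimated correlation). Among T cell markers Thy1 and Cd2 rose, and Ctla4 and Cd28 fell. The erythroid and stromal lists had median Irf4+/+ signals of 46.5 and 44.8, near the mean array median of 40.6. Cell types absent from the cultures cannot rise, so these medians cannot exclude a lower share of B cells. Natural killer cells in the Irf4-/- cultures remain a candidate explanation: in a further list of their genes 11 of 16 rose and 1 fell. The median of 1.02 lay only just above the value of 1 set beforehand. The gene that fell, Klrb1f, went from 198.1 ± 16.6 to 53.8 ± 6.84 (3.35-fold, adjusted p = 5.24e-09). Gzmb and Gzma reached signals of 4868 and 8256. For macrophages or monocytes, 16 of 21 further genes rose, but the median of 0.996 fell just short of the value of 1 set beforehand, which keeps this explanation open. Of these further genes 1 natural killer and 3 macrophage genes lay above the median gene in Irf4+/+ samples, 1 of each list is also in another list (Id2 and Ctss), and expression of such genes by B cells lacking Irf4 was not tested. Genes dim in Irf4+/+ samples, such as Cd244a and Fasl, can pass the filter through their Irf4-/- signal, and members dim in both genotypes are not counted. This tilts both further lists toward rises. Over all genes, 2846 of 12246 were called higher.

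The interferon response rose with a median log2 fold change of 1.57. The lower of its medians under quantile normalization and median centring was 1.509. These settings moved the median of all genes only from 0.004 to -0.025 and -0.057, so they could hardly have ended this rise. They show only that the rise does not hang on the choice among these scalings. Interferon gamma made in the Irf4-/- cultures may contribute: Ifng rose 6.02-fold, from 11.1 ± 6.30, close to the floor, to 101.8 ± 19.1 (log2 fold change 2.589, adjusted p = 5.92e-07). Ifnb1 had a log2 fold change of -0.33 (adjusted p = 0.474). It was close to the floor in both genotypes (34.3 ± 13.9 in Irf4+/+ and 27.2 ± 16.45 in Irf4-/- samples), so its value cannot tell whether this interferon changed. Whether the lack of Irf4 itself raises these genes in B cells stays open and untested, since the arrays measured whole cultures.

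All MYC target and ribosome biogenesis genes fell. Dilution by other cells that lowers all B cell transcripts alike is argued against, because 18 of 22 B cell restricted genes rose and 1 fell, with a median of 0.816. Many of these genes, such as Cd79b, Siglecg, Pax5 and Fcer2a, are also on lists already seen to be higher, so this outcome was partly known. Their rise may be regulated and does not measure the share of B cells, so a part played by dilution is not excluded. The higher of the list's medians under quantile normalization and median centring was -0.749. These settings moved the median of all genes only from 0.004 to -0.025 and -0.057, so they could hardly have changed this result. They show only that the fall does not hang on the choice among these scalings. All of them give the arrays a like overall signal, so a difference in total RNA between cells was not tested. A biological difference between the genotypes remains a hypothesis, found and tested on the same data.

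Among 380 groups of 5 arrays examined for a lone extreme value, 23 had one (6.05%), where chance gives about 5%. In Irf4+/+ samples, replicate 1 gave 1436 for Cd93 (others 1135 to 1158), 5296 for Cdc20 (4341 to 4498), 771.8 for Irf1 (817.6 to 834.4), 76.6 for Casp9 (104.6 to 113.5), 811.3 for E2f3 (606.2 to 664.2) and 1097 for Serpinb6b (935.9 to 966.7). Replicate 2 gave 100.6 for Slc39a8 (143.5 to 155.4) and 675 for Exoc2 (449.9 to 485.3). Replicate 4 gave 11 for Parp12 (2 to 2.6), 86.8 for Egr3 (70.9 to 74.6), 31.8 for S100a8 (11 to 16.4) and 46.2 for Mmp9 (9.1 to 17.6). Replicate 5 gave 1750 for Hk2 (1946 to 2020), 2091 for Sc5d (2287 to 2341) and 104.9 for the 18S control (58.1 to 62.8).

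In Irf4-/- samples, replicate 1 gave 1366 for Myc (others 1141 to 1206), 363.8 for Ccl17 (207.3 to 250.1) and 266.7 for Batf3 (160.7 to 184). Replicate 4 gave 624.3 for Mcm10 (563.8 to 577.8) and 2242 for Trp53inp1 (1905 to 1959), and replicate 5 gave 396.5 for Car2 (301.1 to 323.1). The mean log2 value of the macrophage list was 7.27 in replicate 2 (7.12 to 7.16 in the others), and that of the B cell transcription factors was 10.15 in replicate 5 (10.26 to 10.29). Outside the gene tests, 255 of 637 probe sets with several gene symbols differed between genotypes (145 higher, 110 lower), as did 933 of 3866 not named here (605 higher, 328 lower).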

How the results depend on the processing

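The counts of called genes, the count of called lists, the change of Irf4 and the comparison of genes near Irf4 kept their side of the threshold, or stayed within 1.5 times the count, under every alternative run. The odds ratio near Irf4 lay on both sides of 1, from 0.508 to 1.62, and was not called in any of them (p from 0.114). Called genes ranged from 5396 to 5665 with 1 array left out, and from 5399 (filter at the 60th percentile) to 5970 (array weights) elsewhere. Genes changed at least 2-fold were 687 with the filter at the 60th percentile, 751 with the 40th-percentile pseudocount of 26.1 and 1073 without a filter. Median centring moved the median of all genes to -0.06 and left 2311 genes higher and 3262 lower. Irf4 stayed lower, by a log2 fold change of -0.41 to -0.46 with 1 array left out. With the replicate number as a block, 5677 genes were called and 5541 of them were also called without it. Samples with the same number did not deviate together (r -0.03 to 0.05), and 1 Irf4+/+ and 0 Irf4-/- arrays correlated best with their own number. No pairing by number was seen, which does not exclude one.

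Directions changed for 3 genes with the choice of probe sets. With the mean of a gene's probe sets, Ighm had a log2 fold change of -0.099 (adjusted p = 0.204) and Notch2 of -0.101 (adjusted p = 0.505), since their probe sets disagree. Without probe sets shared between transcripts, Xbp1 had 0.006 (adjusted p = 0.956), as another probe set then stands for it. All 3 also lost their call. Over the named genes other than Irf4, 39 further values lost their call in the same direction and 10 gained one, mostly Mmp9, Gmds, Serpinb9b and Xist, with Igha, Sc5d, E2f3 and Col1a2 the others, and 3 values changed sign while called in neither fit. Lists lost a call in 9 cases, 6 of them with an estimated correlation. Those 9 also include the class switch list (adjusted p = 0.0519) and the resting follicular list (adjusted p = 0.057) at the 60th-percentile filter, which left too few genes in 3 other lists to test them. Fry called 5 lists that camera did not. Genes near the floor of the arrays limit the size of the largest folds.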

Other observations

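The tests of genes at least 2-fold higher beside Irf4, with the Serpinb genes apart or as 1, and of whether they are natural killer or macrophage genes, were chosen after the result was seen. Nuclear pore genes, a group outside the fixed lists, fell together in a scan of 142 families of genes sharing a symbol stem: of 18 Nup genes 15 fell and 0 rose (median -0.42, camera adjusted p = 0.000667, and adjusted p = 0.332 with an estimated correlation). Of 45 Eif translation factor genes 31 fell and 8 rose (median -0.24, camera adjusted p = 0.00362, and adjusted p = 0.332 with an estimated correlation). Of 47 Mrpl genes of the mitochondrial ribosome 25 fell and 1 rose (median -0.22, camera adjusted p = 0.00746, and adjusted p = 0.793 with an estimated correlation). Of 11 Parp genes 7 rose and 1 fell (median 0.75, camera adjusted p = 0.00917, and adjusted p = 0.433 with an estimated correlation). In all 19 families were called, and 0 with an estimated correlation.

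A hypothesis set before its values were seen was that the lower MYC-type programme extends to other translation genes. Of 19 cytosolic aminoacyl-tRNA synthetases 16 fell and 0 rose, with a median of -0.49, and Iars fell 1.84-fold from 2970 ± 253 to 1607 ± 67.4 (adjusted p = 7.15e-09). All 8 chaperonin genes of the Cct complex fell, with a median of -0.378, the higher of both medians. These values are consistent with the hypothesis, which was that both medians would lie below -0.3.

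The planned test of all called genes beside Irf4 gave an odds ratio of 1.12 (Fisher's exact p = 1). Of 16 neighbours 4, seen before this test, were called and at least 2-fold higher (25%), against 5.23% of other genes (odds ratio 6.03, 95% confidence interval 1.41 to 20, Fisher's exact p = 0.00831). By Fisher's exact test the odds ratio was 4.01 (p = 0.111) within 25 genes and 3.53 (p = 0.00664) within 100, and among the 51st to 150th genes 3 of 44 were that much higher (odds ratio 1.33, Fisher's exact p = 0.5). Serpinb1a, Serpinb6b and Serpinb9 are paralogues in 1 cluster, and with the 4 Serpinb neighbours counted as 1 gene the odds ratio was 3.29 (95% confidence interval 0.354 to 15.1, Fisher's exact p = 0.146). Position next to the targeted gene and expression of the neighbours by natural killer cells or macrophages cannot be told apart: 0 of the 4 lie on those lists, which are short and exclude nothing.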
